A study of Rattus norvegicus with 16 samples.

How the data were processed

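RNA from 4 brain regions (amygdala, hippocampus, left cortex and right cortex) of male rats aged 6 or 18 weeks was measured on 16 Agilent 8x60K rat gene expression arrays with 2 colours. Each array carried RNA of the Noda Epileptic Rat (NER) in the Cy3 channel and RNA of the congenic strain NF-Chr1e/5d in the Cy5 channel, per the labels. Each channel held a pool of RNA from 3 rats. With 6 rats per strain and age, the 2 pools of an age together hold those rats in every region. Pools with the same number were taken to hold the same rats in the 4 regions, which the labels do not state, and this gives 4 pool pairs. Whether different regions share rats does not rest on the numbers: each region draws on the same 6 rats per strain and age. The groups were taken from the sample titles, which give region, age and pool number.

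The authors deposited 1 scanner file per array, written by Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. The deposited spot intensity values are median pixel brightness for the spot and for its local background, with no normalization, per the file headers. The same files hold processed intensity values, from which background was subtracted and which were dye-normalized by Feature Extraction, and a log10 ratio of Cy5 over Cy3, per the file headers. The deposited table of values of the series is on a log2 scale: it equals the log10 ratio of each array changed to log2 (correlation 1 on every array, column medians 0). It is therefore NF-Chr1e/5d over NER, opposite in direction to the ratios given here. No spot was saturated.

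For the main values, background was corrected with normexp (offset 50) and each array was normalized by loess over the non-control spots in limma 3.58.1 under R 4.3.3, with version 1.17.8 of the data.table package. The design written beforehand named mean signals, but the files hold medians, which were used in their place. The value of a spot is log2 of NER over NF-Chr1e/5d, so that a positive value means more RNA in NER. Spots marked as non-uniform or as population outliers by the scanner software were left out, and spots of one probe were averaged. Of 30367 probes, 17998 (59.3%) were named by matching their accession, without its version, to the reference table of gene names (assembly GRCr8). The arrays were designed on build rn4, so no coordinates are printed. The other 12369 probes keep the name in the file. A probe was tested if it was well above background in either channel on at least 8 of the 16 arrays (20095 probes), and the brightest probe stood for its gene. This left 17702 features, 10848 with a gene symbol. 2180 genes had more than 1 probe passing.

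The strain difference was tested with limma on 1 value per pool pair (the mean of its 4 regions), with age centred. The strain by age interaction is the age term of that model. Strain differences in each region and age, and the differences between regions, were limma contrasts of 8 group means over the 16 arrays. Those 16 arrays share rats within a pool, so p-values of the contrasts between regions treat as independent what the pools partly share. The age difference was tested on the mean log2 brightness of both channels after quantile normalization of that mean (Aquantile). All p-values were adjusted by Benjamini-Hochberg over the features within a comparison, with a threshold of 0.05. Gene lists were fixed before the data were examined, 30 in number, and 29 had enough measured members to be tested with camera (correlation 0.01, adjusted over lists). A listed symbol that was not tested was matched through an alias where exactly 1 tested gene carries it. This put Ddr1, another gene, in the place of Drd1 in the striatum list. Positions of called genes along chromosomes were scanned in windows of 30 and 15 Mb, the sizes of the replaced segments, in steps of 1 Mb against 1000 permutations of gene positions. The window with the smallest hypergeometric p was taken as the richest. Fisher's exact tests (2-sided) compared chromosomes 1 and 5 with the rest. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

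Genes named in the text follow a rule set before the data were examined. For the strain difference it gives the 14 called genes with the largest change each way among those with the same sign on all 16 arrays. It gives the 3 largest changes each way in each region and age, the 8 largest each way in each interaction, and the 12 largest each way with age. Called members of the gene lists, up to 4 per list by size, and genes the study is known to have picked on these samples (Cckbr, St5 and Phf24) were added. The rule gave 371 genes and comparisons. Some are not reported here, and the text draws on 180 of them, chosen after the values were seen and with preference for features that have a symbol and the largest changes. Sign changes are counted over all 371. St5 and Phf24 were not matched to a probe here.

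The design sets 4 limits on what the values can show. NER was Cy3 and NF-Chr1e/5d Cy5 on every array, so a bias of the dye on a probe and a strain difference cannot be told apart. A dye bias that is constant per probe cancels in the interactions. One that differs between the slides does not cancel in the strain by age interaction. The 8 arrays at 18 weeks shared a slide and the 8 arrays at 6 weeks shared another, so slide and age cannot be told apart, and a slide as a block could not be run. With 4 pool pairs, p-values measure the spread between pools. The number of arrays limits the precision.

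Pairing by pool rests on the shared pool numbers and on rats that the regions have in common. Deviations of same-numbered arrays from their group means correlated between 0.04 and 0.372 over 12 pairs of regions, 9 of them above 0.1, and the consensus correlation of the block was 0.1. Blocked counts stand beside the strain, age and interaction counts that they raise.

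The tests were run on simulated data over 17702 features with 50 changed genes at each of 4 fold sizes. At 1.25-fold the strain comparison recovered 100% of the changed genes, the strain by age interaction 24%, the amygdala against cortex contrast 62% and the age comparison 80%. At 1.5-fold these shares were 100%, 90%, 94% and 96%. False calls numbered 17 for strain, 4 for strain by age, 4 for amygdala against cortex and 5 for age. With the pool as a block they numbered 43, 18, 5 and 24. The simulated values held no dye bias of probes and no slide effect. These shares and false calls therefore do not cover errors from dye in the strain comparison or from slide in the age comparison.

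The alternatives tried were: no background subtraction, the median of each array in place of loess, log ratios scaled between arrays, Agilent's processed signals, the deposited value table, no filter on dim probes, a stricter filter, the mean of all probes of a gene, the pool as a random block, a 1.5-fold minimum, each pool or array left out, the methods' t-test, and an estimated correlation between list members. Chosen after the data were seen were the recentred version of the median setting, 3 position scans that change fold and globin counting together, the correlation estimated from all 16 arrays, and list medians with each pool left out.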

Results

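The Noda Epileptic Rat (NER) is an inbred strain with spontaneous generalized tonic-clonic seizures. It was compared with NF-Chr1e/5d, a seizure-resistant strain on the NER background in which segments of 30 Mb on chromosome 1 and 15 Mb on chromosome 5 come from the F344 strain. The comparison asks which genes differ in brain RNA between the strains, in amygdala, hippocampus and left and right cortex, at 6 and 18 weeks of age. The brains were taken at least 2 h after any observed seizure. The data are 16 arrays with 2 arrays for each of 8 combinations of region and age. Probes well above background made up 62.9% to 69.6% of each array in the NER channel and 68.9% to 72.7% in the NF-Chr1e/5d channel. Log ratios of the 2 arrays of a group correlated across genes between 0.467 and 0.705. Relative to their own mean over regions, genes listed for hippocampus had a median brightness of 0.63 log2 in hippocampus arrays, those listed for amygdala 0.13 in amygdala arrays and those listed for cortex layers 0.15 in cortex arrays. Genes listed for striatum, which was not dissected, stood at 0.54 in amygdala arrays.

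Averaged over regions and ages, the largest named strain differences were in genes of red blood cells, which were lower in NER. The beta globin genes Hbe2 (log2 ratio -2.10, SE 0.03) and Hbb (-2.04, SE 0.03), the alpha globin gene Hba-a1 (-1.74, SE 0.04), Hbb-b1 (-1.73, SE 0.03) and Hba-a3 (-0.70, SE 0.03) were lower on all 16 arrays. Hba-a3 was well above background in NER on 6 of the 16, so its ratio rests on a dim channel. Alas2, the erythroid enzyme of heme synthesis, was lower as well (-1.15, SE 0.04). One beta globin, Hbb-bs, went the other way and was 1.53-fold higher in NER (0.61, SE 0.03), a call lost without loess (0.03, adjusted p = 0.397). Some globin genes of one family are near-identical copies, so their probes may share signal, which was not tested. Of 8 measured genes on the list of blood genes, 6 were lower and none higher (adjusted p = 0.000288 by camera, adjusted p = 0.737 with an estimated correlation; 6 adjusted over the list alone).

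Outside blood, the cholecystokinin B receptor gene Cckbr, which the study picked on these samples and which is therefore no independent evidence, was lower in NER (-1.0, SE 0.03, adjusted p = 6.46e-06, lower on 16 of 16 arrays). Its second probe gave -0.49. Also lower were Snap25, a vesicle fusion protein (-0.69, SE 0.03), Slc32a1, the vesicular GABA transporter (-0.69, SE 0.03), and Gad1, an enzyme of GABA synthesis (-0.68, SE 0.03). The second probe of Snap25 gave -0.69, but that of Gad1 gave 0.01. Atp1b1, a sodium pump subunit (-0.66, SE 0.04), Apc2 (-0.65, SE 0.04), Tmem130 (-0.60, SE 0.03) and the stress-induced factor Atf3 (-0.79, SE 0.09) complete the named decreases, with a second probe of Apc2 at -0.06. An unnamed feature, XM_575808, was lowest of all, 13.5-fold lower (-3.76, SE 0.08). Another, XM_002729465, was not well above background in NER and was at least 2.8-fold lower there, with both channels after loess and quantile scaling and open to dye bias.

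The genes higher in NER were led by Rpph1, the RNA component of RNase P (1.08, SE 0.03, 2.11-fold). Rims1, a gene of the synaptic release site (0.64, SE 0.03), Erc2 of the same structure (0.50, SE 0.03) and the synaptic vesicle gene Syn2 (0.52, SE 0.04) were higher. Gabrg1, a GABA-A receptor subunit (0.58, SE 0.03), the sodium bicarbonate transporter Slc4a10 (0.51, SE 0.03) and Ugt8, an enzyme of myelin lipid synthesis (0.50, SE 0.04), were higher too. Pdlim5 (0.56, SE 0.03), the protein kinase A subunit Prkacb (0.55, SE 0.03), Cpeb4 (0.54, SE 0.03), Foxe1 (0.54, SE 0.03), Polm (0.51, SE 0.03) and Reep3 (0.49, SE 0.03) complete the list. Each was higher on 16 of 16 arrays, with adjusted p between 8.72e-06 and 0.000174 in limma. Without loess, Prkacb, Cpeb4, Syn2, Polm, Erc2 and Reep3 changed sign, with values between -0.11 and -0.001, and they kept their sign relative to the median of the tested features, a comparison chosen after the sign changes were seen. Foxe1 (0.04, adjusted p = 0.239) and Slc4a10 (0.006, adjusted p = 0.855) lost their call without loess. Second probes gave 0.14 for Slc4a10, 0.21 for Erc2, 0.30 for Reep3 and 0.38 for Cpeb4.

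Among the gene lists, immediate early genes, which respond to neuronal activity, were lower in NER in the mean over ages: 23 of 28 fell and 1 rose (adjusted p = 1.36e-05; adjusted p = 0.737 with an estimated correlation; 24 adjusted over the list alone). Egr4 (-0.82, SE 0.08), Fos (-0.80, SE 0.10) and Nr4a1 (-0.66, SE 0.08) were among them. Of 19 activity-regulated neuropeptides and secreted factors, 13 were lower and none higher (adjusted p = 0.00112; adjusted p = 0.737 with an estimated correlation; 13 adjusted over the list alone). These included Scg2 (-0.50, SE 0.04), Npy (-0.50, SE 0.03), Tac1 (-0.45, SE 0.03) and Pdyn (-0.34, SE 0.06). Second probes gave -0.20 for Npy and -0.20 for Tac1. Of 18 cholesterol synthesis genes, 10 were lower and none higher (adjusted p = 0.0222; adjusted p = 0.737 with an estimated correlation; 11 adjusted over the list alone), with Insig1 at -0.40 (SE 0.05), Fdps at -0.28 (SE 0.03), Sc5d at -0.23 (SE 0.03) and Nsdhl at -0.22 (SE 0.03). The second probe of Fdps gave -0.02. Of 16 interneuron markers, 10 were lower and 2 higher (adjusted p = 0.0265; adjusted p = 0.737 with an estimated correlation; 12 adjusted over the list alone), among them Vip (-0.35, SE 0.07). The other 24 lists were not called, with adjusted p from 0.0827 to 0.971.

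Several lists held genes that moved both ways. Of 23 genes for GABA synthesis, transport and receptors, 7 were higher, Gabra4 among them (0.45, SE 0.03), and 7 lower. Of 43 human monogenic epilepsy genes, 11 were higher and 15 lower. Of 43 voltage-gated ion channel genes, 11 were higher and 13 lower: Kcnd3 was at 0.46 (SE 0.04) and Scn8a at 0.37 (SE 0.05), against Scn4b at -0.55 (SE 0.09) and Kcnc1 at -0.39 (SE 0.04). Myelin genes split likewise, 4 higher and 4 lower of 17: Mbp was at -0.63 (SE 0.06), Mobp at 0.49 (SE 0.06) and Mog at 0.36 (SE 0.05). A second probe gave 0.03 for Mbp and -0.31 for Mobp, and without loess Mobp was at -0.15 and Mog at -0.24. Gabra4 (0.02, adjusted p = 0.511), Kcnd3 (0.08, adjusted p = 0.118) and Scn8a (0.001, adjusted p = 0.990) lost their call without loess. Neurod1, listed among mossy-fibre and dentate granule markers, was higher (0.45, SE 0.04).

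In all, limma called 8748 of 17702 features, 4101 higher and 4647 lower in NER (46.9% higher), with a median size of 0.16 log2. The larger count rests on small differences: 40 of them reached 1.5-fold, 13 higher and 27 lower. Of the features with a symbol, 23 reached 1.5-fold, against 354 with Agilent's processed signals. With the pool as a block 9935 features were called. Without loess, the median of all tested features shifted from -0.01 to -0.27, and 16210 features were called, 31.9% of them higher.

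**Figure D1:**
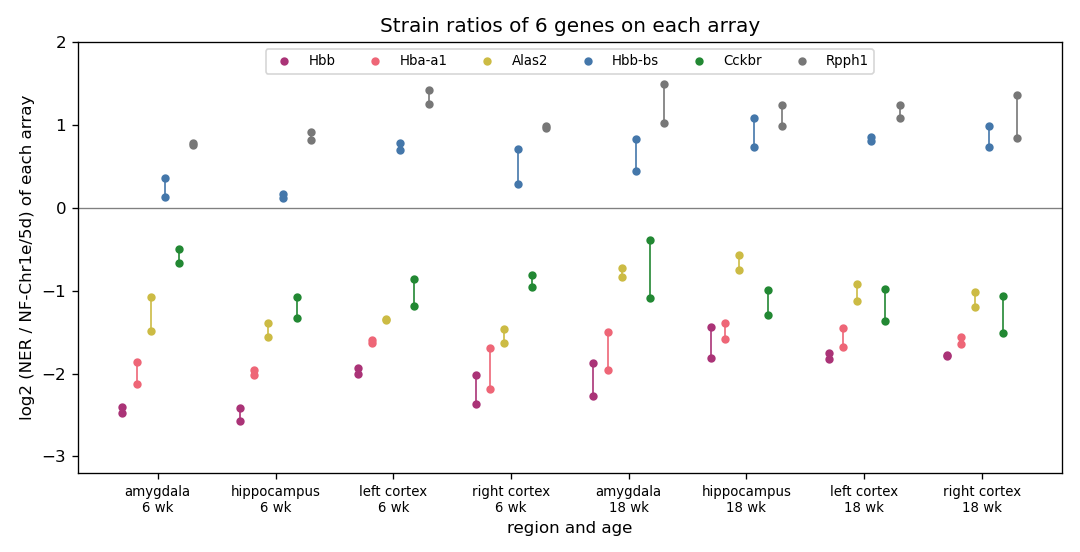
Strain ratios of 6 genes on each array. The vertical axis gives log2 of NER over NF-Chr1e/5d, the horizontal axis the 8 combinations of region and age, each point is 1 array and a line joins the 2 arrays of a group. Hbb, Hba-a1, Alas2 and Cckbr lie below 0 on all 16 arrays, and Hbb-bs and Rpph1 above 0.

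The beta globins Hbe2 and Hbb were lower in every region and age. Hbe2 ranged from -2.56 (hippocampus at 6 weeks, SD 0.03, n = 2) to -1.71 (hippocampus at 18 weeks, SD 0.30, n = 2), and Hbb from -2.49 to -1.63 in the same groups. In the amygdala, Rasl10a was higher in NER at both ages (1.31 and 1.35), and Avp, the vasopressin gene, was lower (-3.76 at 6 weeks and -2.60 at 18 weeks), though the 2 arrays at 18 weeks gave -4.64 and -0.56. Rln1 (1.19) and Slc35e2b (1.28, SD 1.58) were higher in amygdala at 6 weeks, and Rpph1 (1.26) and Srpk3 (1.00) at 18 weeks. In the hippocampus at 6 weeks, choroid plexus genes were higher in NER: Ttr, the transthyretin gene (6.72, SD 0.79, n = 2), Folr1 (3.18, SD 0.37, n = 2) and Kcnj13 (2.39, SD 0.43, n = 2). Over 12 alternatives the call was lost in 4 for Ttr, 3 for Kcnj13 and 0 for Folr1. Values stayed at or above 6.075 for Ttr and 2.086 for Kcnj13. Of 9 measured choroid plexus and ependyma markers, 6 were higher there and none lower, with a median of 1.55. In amygdala at 6 weeks 4 of the 9 were lower, with a median of -0.85. In the hippocampus at 18 weeks 1 of the 9 was higher, with a median of 0.07, and Ttr was at -1.74 (SD 7.26, n = 2), not called. In the hippocampus at 18 weeks, Rxrg (1.58), the serotonin receptor gene Htr2c (1.28) and Nr2f2 (1.16) led the increases.

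In the left cortex, Rpph1 was at 1.34 at 6 weeks and 1.17 at 18 weeks, with Msl3l2 (0.90) and Gabrg1 (0.87) at 6 weeks, and Hbb-bs (0.83) and Cbln1 (0.74) at 18 weeks. In the right cortex, Rpph1 was at 0.98 and 1.11, with Bst2 (0.75) and Sesn3 (0.70) at 6 weeks, and Hbb-bs (0.87) and Lipt2 (0.62) at 18 weeks. The immediate early genes Egr4 (-1.89 in left and -2.0 in right cortex) and, in right cortex, Atf3 (-1.84) stood among the lowest genes at 18 weeks. limma called 3930 features in amygdala, 1720 in hippocampus, 4005 in left cortex and 2635 in right cortex at 6 weeks, and 2709, 3114, 2904 and 2400 at 18 weeks. Of 8268 features called in at least 1 group, 471 were called in all 8, and 470 of these had one sign. Whatever the sign, 9 features were also at least 1.5-fold in all 8 groups: Hbe2, Hbb, Hba-a1, Hbb-b1, Alas2, Rpph1 and the unnamed XM_575808, XM_002729465 and NM_212504. NM_212504 did not keep one sign: on average it was higher in NER at 6 weeks and lower at 18 weeks.

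These counts rest on 2 arrays a group. Leaving out array 1 or array 2 left 745 or 1948 calls in amygdala, 60 or 340 in hippocampus, 2448 or 380 in left cortex and 166 or 82 in right cortex at 6 weeks. At 18 weeks it left 1699 or 381, 166 or 1906, 153 or 897, and 430 or 379, the lone array being assumed to vary like the other groups. Without loess, 28.9% to 30.3% of calls in a group were higher in NER, against 44.8% to 55.3% in the main values. Among calls of at least 1.5-fold the share ranged more widely. It ran from 7.5% of 106 in right cortex at 18 weeks to 81.8% of 253 in left cortex at 6 weeks.

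The strain ratio of immediate early genes differed between the arrays at 6 and 18 weeks, which were on different slides. Their strain ratio was lower at 18 weeks than at 6 weeks by a median of 0.49 on the log2 scale (median change -0.49 over 28 genes; adjusted p = 7.23e-36 by camera, adjusted p = 0.520 with an estimated correlation). Egr4 changed by -1.50 (SE 0.15, adjusted p = 0.0394), from -0.07 at 6 weeks to -1.58 at 18 weeks. Nr4a3 changed by -1.0 (SE 0.08, adjusted p = 0.0262) and Egr1 by -0.88 (SE 0.08, adjusted p = 0.0262). Within groups the lower calls came from 18 weeks: 13 of the 28 in amygdala, 15 in hippocampus, 23 in left and 25 in right cortex, with none higher. At 6 weeks 5 were higher and none lower in amygdala, 1 was lower in hippocampus, 2 were lower in left cortex and 1 was higher in right cortex. Egr4, Nr4a3 and Egr1 were the 3 members called over all features for the change with age, against 24 adjusted over the list alone. By channel, the list rose by a median of 0.53 from 6 to 18 weeks in NF-Chr1e/5d, where 27 of 28 genes went up, and changed by -0.06 in NER, where 9 of 28 went up. Single genes departed from that median: Egr4 fell by 0.82 in NER and rose by 0.68 in NF-Chr1e/5d, and Egr2 fell by 0.52 in NER. A channel's change between ages holds any difference between slides, so it cannot tell which strain changed. The ratio also holds any dye bias that differed between the slides. A change of the strain difference with age cannot be told apart from such a bias.

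Other lists differed between the ages in the same test, with the same limit from the slides. The strain ratio of blood genes rose by a median of 0.31 (adjusted p = 3.45e-11; adjusted p = 0.520 with an estimated correlation), so their deficit in NER was smaller at 18 weeks. No list member was called over all features. Hba-a3, an alpha globin gene that is not on the list, was called at 0.56 (SE 0.05), but it was well above background in NER on 6 of 16 arrays, so a fall in NF-Chr1e/5d alone would shrink its ratio. Ratios rose for myelin genes (median 0.26, adjusted p = 3.85e-12), microglia (0.08, adjusted p = 0.000559), oligodendrocyte precursors (0.11, adjusted p = 0.00226) and interferon-stimulated genes (0.13, adjusted p = 0.00800). Ratios of heat shock and protein folding genes (median -0.22, adjusted p = 3.59e-08) and of meninges and fibroblast genes (-0.21, adjusted p = 0.000807) were lower at 18 weeks. With an estimated correlation the adjusted p of these lists was 0.520, and 0.563 for meninges. Adjusted over the list alone, 7 blood, 12 myelin, 5 heat shock, 3 interferon-stimulated and 0 microglia, precursor or meninges genes were called.

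Over all features limma called 7 for this interaction, 1 higher and 6 lower, and 120 with the pool as a block. The largest was the unnamed NM_212504 (-3.34, SE 0.17), which went from 0.98 to -2.36, and XR_006670 changed by -0.94 (SE 0.08). Without 18-week pool 1 the count was 85, without 18-week pool 2 it was 107, and without 6-week pool 2 it was 0. Of the 6 features named for this interaction, 3 stayed called without 6-week pool 1 and 0 without 6-week pool 2. Agilent's processed signals, the deposited value table and values without background subtraction gave 0, no filter on dim probes gave 1, and values without loess gave 252 higher and 92 lower, 73.3% higher against 14.3%.

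**Figure D2:**
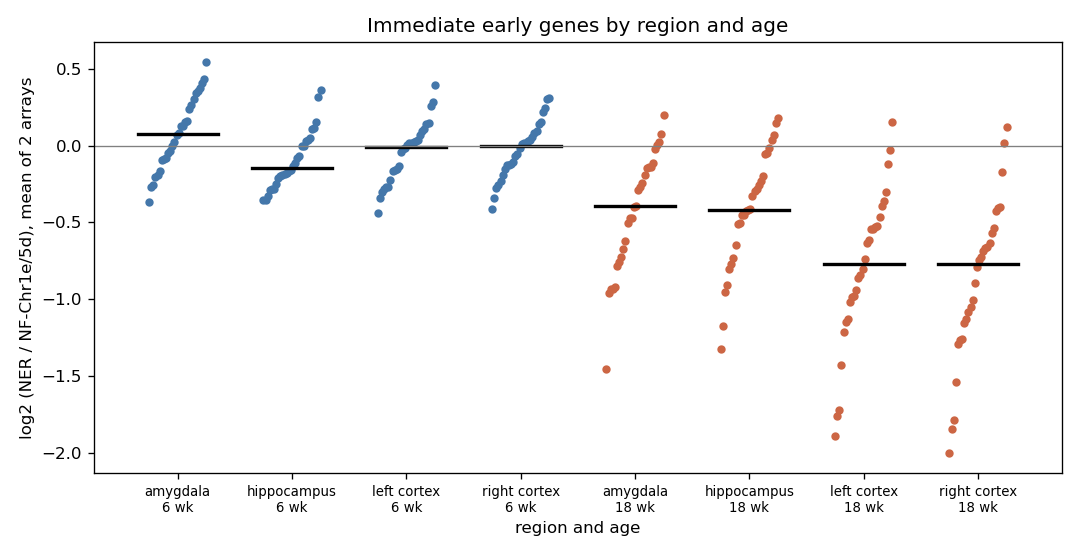
Immediate early genes by region and age. The vertical axis gives log2 of NER over NF-Chr1e/5d (mean of 2 arrays), the horizontal axis the 8 combinations of region and age, each point is 1 of 28 genes, ordered by value, and bars are medians. Medians lie between -0.15 and 0.08 at 6 weeks and between -0.77 and -0.40 at 18 weeks.

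The strain difference differed between amygdala and cortex in both directions. The strain ratio was lower in amygdala than in cortex for Avp (-3.16, SE 0.48), the serotonin receptor gene Htr2c (-0.95, SE 0.11) and the adenosine receptor gene Adora2a (-0.88, SE 0.20). It was lower too for the peptide genes Nts (-0.74, SE 0.14) and Penk (-0.70, SE 0.12), and for Cabp7 (-0.72, SE 0.12), Cbln1 (-0.72, SE 0.13) and 6330403K07Rikl (-0.68, SE 0.12). The ratio was higher in amygdala than in cortex for Rasl10a (1.35, SE 0.07), Grem1, a secreted BMP antagonist (1.16, SE 0.09), and the relaxin gene Rln1 (1.14, SE 0.11). The same held for Rasgef1c (0.91, SE 0.20), Trim54 (0.90, SE 0.11) and the synaptic zinc transporter gene Slc30a3 (0.90, SE 0.09). So it was for the steroid enzyme genes Cyp11b1 (0.81, SE 0.16) and Cyp11b3 (0.80, SE 0.14). Such a difference of ratios can come from either tissue. Some of these probes were dim: those of Rln1, Trim54, Cyp11b1, Cyp11b3, Avp, Nts and Cbln1 were not well above background in both channels on every array. Over 14 alternatives the call was lost in 5 for Cyp11b1 and 4 for Cyp11b3. Of 13 genes tested for the striatum list, 2 (Adora2a and Penk) were lower and none higher, with a median of -0.49. One of the 13 is Ddr1, matched in error through an alias of Drd1, and it was not called. Of 19 activity-regulated neuropeptides and secreted factors, 3 were higher and 3 lower. limma called 218 features (155 higher, 63 lower), 37 of them at least 1.5-fold, and 331 with the pool as a block. Without 6-week pool 1 the count was 40, and without 6-week pool 2 it was 3, leaving 8 and 2 of the 16 genes named here. Processed signals and the deposited value table each gave 132, and values without loess gave 1262, 57.2% of them higher against 71.1%.

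Averaged over the ages, the strain ratio was higher in hippocampus than in cortex for the following genes. Folr1, a folate receptor (2.06, SE 0.33), the keratin gene Krt18 (1.32, SE 0.21), the dynein gene Dynlrb2 (1.05, SE 0.20), the water channel gene Aqp1 (1.00, SE 0.19) and Foxj1, a regulator of motile cilia (0.71, SE 0.11), were higher. So were Smim22 (0.91, SE 0.16), Kcnk16 (0.85, SE 0.16) and Steap1 (0.67, SE 0.12). Some of these probes were dim: Steap1 was well above background on 3 of 16 arrays in NER and 8 in NF-Chr1e/5d, Aqp1 on 7 and 11, and Folr1 on 8 and 15, so their differences are imprecise. Of 9 choroid plexus and ependyma markers, 3 were higher and none lower, with a median of 0.92. Their strain medians in hippocampus itself were 1.55 at 6 weeks and 0.07 at 18 weeks. In amygdala at 6 weeks their median was -0.85. It was not tested whether the strains' dissected tissue held the same amount of choroid plexus. Ucp2, a mitochondrial carrier, was lower (-0.88, SE 0.09), as were Ccdc27 (-0.68, SE 0.12), Nmb (-0.52, SE 0.08), Gucy1a1 (-0.48, SE 0.08), B3gat2 (-0.48, SE 0.06) and the neurotrophin gene Ntf3 (-0.46, SE 0.08), which was well above background on 7 arrays in NER and 6 in NF-Chr1e/5d. limma called 43 features (33 higher, 10 lower), 20 of them at least 1.5-fold, and 73 with the pool as a block. Without 6-week pool 1 the count was 1, without 6-week pool 2 it was 6, and without 18-week pool 2 it was 81, and 1, 0 and 10 of the 14 genes named here stayed called. Processed signals gave 9, 8 in the deposited values, values without background subtraction 11, the stricter filter 16, and values without loess 606, 55.3% of them higher against 76.7%.

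Between left and right cortex, limma called 0 features for a difference in the strain ratio, with 750 at an unadjusted p under 0.05. Ubfd1 (-0.26, SE 0.06), Btg3 (-0.29, SE 0.06) and Dcaf12l1 (-0.27, SE 0.06) had the smallest p and did not pass (adjusted p = 0.996). Processed signals, the deposited value table and the values without 18-week pool 1 each gave 1.

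In the mean of both strains, meninges and fibroblast genes and blood genes were lower at 18 weeks than at 6 weeks. The collagen genes Col1a1 (-1.77, SE 0.09) and Col1a2 (-1.49, SE 0.16), the growth factor gene Igf2 (-1.46, SE 0.13) and its binding protein gene Igfbp2 (-1.40, SE 0.11) fell. Of 13 meninges and fibroblast genes, 10 were lower and none higher (adjusted p = 0.000117; adjusted p = 0.851 with an estimated correlation and 0.156 with the pool as a block; 10 adjusted over the list alone). Of 8 blood genes, 7 were lower (adjusted p = 0.000569; adjusted p = 0.851 with an estimated correlation; 7 adjusted over the list alone), with Hbb at -1.24 (SE 0.08) and Hba-a1 at -1.07 (SE 0.07). The beta globin genes Hbe2 (-1.59, SE 0.08) and Hbb-bs (-1.33, SE 0.08), which are not on the list, were lower too. Blood was the list still called with the pool as a block (adjusted p = 0.00173). Glul, the glutamine synthetase gene (-1.71, SE 0.07), the somatostatin gene Sst (-1.33, SE 0.04), Ttr (-1.45, SE 0.34; adjusted p = 0.0556 with processed signals), Nudt9 (-1.58, SE 0.03), Eif3h (-1.57, SE 0.05) and Rtn4rl1 (-1.43, SE 0.03) were lower too, and so were Tmsb10 (-1.19, SE 0.04) and Marcksl1 (-0.70, SE 0.05), which are listed for young neurons.

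Myelin genes were lower in 10 of 17 cases and higher in none (adjusted p = 0.000569; adjusted p = 0.890 with an estimated correlation and 0.323 with the block; 10 adjusted over the list alone), with Ugt8 at -1.01 (SE 0.07), Cldn11 at -0.60 (SE 0.07) and Mal at -0.53 (SE 0.07). Of 10 oligodendrocyte precursor genes, 5 were lower and 1 higher (adjusted p = 0.0432; adjusted p = 0.851 with an estimated correlation and 0.631 with the block; 7 adjusted over the list alone): Olig1 (-0.36, SE 0.04), Olig2 (-0.29, SE 0.05) and Pdgfra (-0.25, SE 0.03) fell and Bcas1 rose (0.32, SE 0.07). Of 18 cholesterol synthesis genes, 7 were lower and 1 higher (adjusted p = 0.0445; adjusted p = 0.851 with an estimated correlation and 0.356 with the block; 9 adjusted over the list alone), with Fdft1 at -0.42 (SE 0.03) and Sqle at -0.40 (SE 0.04). Of 9 choroid plexus and ependyma genes, 5 were lower (adjusted p = 0.0306; adjusted p = 0.851 with an estimated correlation and 0.689 with the block; 5 adjusted over the list alone).

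Microglia genes went the other way: 12 of 17 were higher and 1 lower (adjusted p = 0.0103; adjusted p = 0.851 with an estimated correlation and 0.155 with the block; 13 adjusted over the list alone). Trem2 (0.53, SE 0.04), Aif1 (0.38, SE 0.03) and C1qb (0.36, SE 0.03) rose, and Cx3cr1 fell (-0.51, SE 0.05). Of 28 immediate early genes, 5 were higher and none lower (adjusted p = 0.0445; adjusted p = 0.890 with an estimated correlation and 0.323 with the block; 4 adjusted over the list alone). The largest named increases were Qdpr (0.79, SE 0.05), Gadd45b (0.69, SE 0.08), the complement gene C3 (0.67, SE 0.05), Pbld1 (0.64, SE 0.07), Aadat (0.61, SE 0.04), Serinc2 (0.61, SE 0.05), Ptpn11 (0.58, SE 0.03), Pla2g7 (0.57, SE 0.05), Rbm3 (0.54, SE 0.05), RT1-T18 (0.54, SE 0.03), Hspb1 (0.54, SE 0.07) and Stk32c (0.53, SE 0.08). Such a mean can rest on one strain: Hspb1 changed by -0.13 in NER and 1.21 in NF-Chr1e/5d, and Gadd45b by 0.29 and 1.08. limma called 8080 features, 4510 higher and 3570 lower (9604 with the pool as a block), and of the 661 that reached 1.5-fold 10 were higher and 651 lower. Slide and age cannot be told apart, so these values may hold differences between slides.

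Called genes were set against the sizes of the replaced segments, whose ends the sources used here do not give. Of genes on chromosomes 1 and 5, 47.8% were called for strain, against 48.6% elsewhere (Fisher's exact test, 2-sided, p = 0.494). The richest window of 30 Mb by a hypergeometric test lay on chromosome 17, with 16 of 18 genes called, and windows as rich occurred among permuted positions (permutation p = 0.183). Among the 23 genes with a symbol that also reached 1.5-fold, Hbb-bs, Hbb-b1, Hbb, Hbe2 and Cckbr lay within one window of 15 Mb on chromosome 1 that held 79 tested genes (permutation p = 0.001, the smallest the permutations can give). 10 tested genes lie between Hbb and Cckbr in the reference order. With globin genes counted once, a test chosen after this window was seen, the richest window of 15 Mb lay on chromosome 3, with a permutation p of 0.507. In a fixed window of 30 Mb on chromosome 1 centred between Cckbr and St5, 5 of 173 genes were called and at least 1.5-fold, against 18 of 10675 elsewhere (Fisher's exact test, 2-sided, p = 2.6e-05), and 16 of 173 with processed signals, a combination chosen after the data were seen (p = 0.000168). Without the fold minimum 85 of the 173 were called (the same exact test, p = 0.878). In a fixed window of 15 Mb on chromosome 5 centred on Phf24, 0 of 85 genes were called and at least 1.5-fold (exact p = 1), 4 with processed signals (exact p = 0.360), and 38 without the fold minimum (exact p = 0.515). The 5 on chromosome 1 are Cckbr, which the study picked on these samples, and beta globin genes, some of them near-identical copies, so they are not independent.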

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

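Chosen after the results were seen were the tests of second probes, of chromosomes 1 and 5 and of the 3 explanations for the globin genes, the test of the NER channel in immediate early genes, and the list medians with a pool pair left out, whose bound was set before those medians were computed. Reassigned strain signs, relabelled regions and matched random lists were set before their results were seen.

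By the test of the interaction, the strain difference of immediate early genes had a median change of -0.49 from 6 to 18 weeks (not called with a correlation estimated from the pool means, adjusted p = 0.520), with Egr4 at -1.5, Nr4a3 at -1.0 and Egr1 at -0.88. The lowest median among 10000 random lists matched on brightness was -0.079. Loess had already centred the ratios at each brightness on every array, so medians of random lists had to lie near 0. The lists therefore cannot test a shift shared by genes of one brightness. They show only that the list stood apart from other genes of its brightness, and random genes do not vary together as list members may. Leaving out each pool pair gave medians up to -0.424, which argues against 1 pool pair as the source. The NER channel changed by a median of -0.059 (95% bootstrap interval -0.19 to 0.014). A channel's change between ages holds any difference between slides, and the interval resamples genes and not pools. It therefore cannot decide whether NER fell or NF-Chr1e/5d rose, for the list or for single genes. By channel, Egr4 changed by -0.82 in NER and 0.68 in NF-Chr1e/5d, and 9 of 28 genes went up in NER against 27 in NF-Chr1e/5d. Age, the state of the animals at sampling and a slide effect on these probes stay open, since slide and age cannot be told apart.

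The globin genes Hbe2, Hbb, Hbb-b1, Hba-a1 and Hba-a3 and the gene Alas2 were lower in NER on all 16 arrays, while Hbb-bs was higher on 16 and Hbg1 was at 0.004, and the median of the blood list moved with age by 0.31, with Hba-a3, outside the list and dim in NER, at 0.56. A beta globin haplotype on chromosome 1 as the whole source is argued against by erythroid genes on other chromosomes, whose median was -1.15. Less blood RNA of every kind is argued against by the neutrophil genes S100a8 (-0.02) and S100a9 (-0.20, adjusted p = 0.00196), whose median was -0.11, though a smaller loss of blood RNA stays open. Of 13 detected erythroid probes 11 were lower (84.6%), just short of the 85% set as the bound against a dye bias of single probes, so dye bias cannot be told apart from strain here, and probes of near-identical genes are not independent. A difference in red cells or their precursors between the strains stays open and was not tested.

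The many small strain differences are the third pattern. Of 1219 called genes under 1.5-fold with a second detected probe, 61.3% had the same sign on it (95% interval 58.5 to 64), a share that is consistent with a dye bias of single probes for many of them. Genes on chromosomes 1 and 5 were called in 47.76% of cases against 48.63% elsewhere, so calls were no denser on these chromosomes. Fixed windows of the segments' sizes held 173 and 85 tested genes, too few to make up most calls whatever the outcome. The comparison therefore cannot decide whether the segments are the source, and effects of the segments on genes elsewhere were not tested. Of 8 assignments of strain sign to the 4 pool pairs, 1 called as many features (8748, against 7 at most in the others), and 8 assignments are too few for a share under 0.05. Real strain differences across the genome stay open for any single gene.

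The test of the interaction called 7 features and 8 gene lists for a change with age, and none of the 8 lists with a correlation estimated from the pool means (adjusted p = 0.520, and 0.563 for meninges). Lists other than immediate early and blood genes had medians of 0.26 for oligodendrocytes and myelin, -0.22 for heat shock and protein folding stress, 0.08 for microglia, -0.21 for meninges and fibroblasts, 0.11 for oligodendrocyte precursors and 0.13 for interferon-stimulated genes. Adjusted over the list alone, 0 microglia, precursor or meninges genes were called. The unnamed features NM_212504 and XR_006670 changed by -3.34 and -0.94.

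The strain difference differed between amygdala and cortex in 218 features by the test of the interaction. The 13 genes tested for striatum, which was not dissected, had a median of -0.49 in this contrast. Of these 2 were called, both lower, and 1 was matched in error. Whether the dissected tissue was alike between the strains was not tested. Of 100 labellings of the regions within pools, the real one included, 1 called as many, and the highest other called 66. That is the smallest share 100 labellings can give, and it concerns the count and not single genes. With a pool left out the count fell to as few as 3. The named values were 1.35 for Rasl10a, 1.16 for Grem1, 1.14 for Rln1, 0.91 for Rasgef1c, 0.90 for Trim54, 0.90 for Slc30a3, 0.81 for Cyp11b1 and 0.80 for Cyp11b3. They were -3.16 for Avp, -0.95 for Htr2c, -0.88 for Adora2a, -0.74 for Nts, -0.72 for Cabp7, -0.72 for Cbln1, -0.70 for Penk and -0.68 for 6330403K07Rikl.

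The strain difference differed between hippocampus and cortex in 43 features. Of 9 choroid plexus and ependyma markers 3 were among them, all higher. The strain median of these markers in hippocampus was 1.55 at 6 weeks, with 6 of 9 called higher, and 0.07 at 18 weeks. In amygdala at 6 weeks it was -0.85, with 4 of 9 called lower and none higher. These values argue against a strain difference of these markers that is alike across regions. Whether the dissected tissue was alike between the strains was not tested. Of 100 labellings 1 called as many, the smallest share they can give, and the highest other called 5. This too concerns the count and not single genes, and with a pool left out the count fell to as few as 1. The named values were 2.06 for Folr1, 1.32 for Krt18, 1.05 for Dynlrb2, 1.00 for Aqp1, 0.91 for Smim22, 0.85 for Kcnk16, 0.71 for Foxj1 and 0.67 for Steap1. They were -0.88 for Ucp2, -0.68 for Ccdc27, -0.52 for Nmb, -0.48 for Gucy1a1, -0.48 for B3gat2 and -0.46 for Ntf3. Between left and right cortex the real count was 0, so that 100 of 100 labellings had to call as many, and the highest other called 11. That count says nothing about chance.

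Among control spots, which no comparison uses, (+)E1A_r60_a22 had a Cy5 signal of 118.8 against 65 for the negative control 3xSLv1. It was picked as the highest of the E1A spots, and the others ranged from 67.3 to 107.8. The scanner software's correlation of observed with expected spike-in values was between 0.569 and 0.682 over the arrays.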

How the results depend on the processing

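Chosen after the data were seen were the values relative to the median without loess, the globin and processed-signal position scans, the correlation from 16 arrays and the list medians under each setting. A slide block was not run, since slide and age cannot be told apart, and the deposited values and the scaling give no age result. Signal over background limits the dim probes. Where no reason is given the cause was not tested.

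Without loess the calls were 16210 for strain, 3.4e+02 for strain by age (252 higher and 92 lower), 1262 for amygdala against cortex, 606 for hippocampus against cortex, and 13327, 13137, 14379 and 13905 in amygdala, hippocampus, left and right cortex at 6 weeks and 14076, 14023, 13829 and 13862 at 18 weeks. The median strain log2 ratio then moved from -0.01 to -0.27, and the ratio followed brightness across genes (rho -0.9, against 0.06). Of 371 genes and comparisons the naming rule gives, 36 reversed there, 8 of them among the 180 in the text: Prkacb -0.034, Cpeb4 -0.025, Syn2 -0.10, Polm -0.11, Erc2 -0.08, Reep3 -0.001, Mobp -0.15 and Mog -0.24. Another 11 of the 180 lost their call: Hbb-bs, Foxe1, Slc4a10, Gabra4, Kcnd3 and Scn8a for strain, Aqp1 and Gucy1a1 for hippocampus against cortex, and Msl3l2, Sesn3 and Srpk3 in 1 region and age each. More calls in the text were lost under other settings: 30 with processed signals, 29 with the deposited values, 20 without background subtraction and 12 with no filter. Relative to the median, a setting chosen after the reversals without loess were seen, 23 of 253 reversed, 0 of them in the text. There 4 genes in the text lost their call, Mobp and Mog among them. The mean of all probes reversed 2 and leaving out a pool or array reversed 2, 0 of them in the text.

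Strain by age gave 0 calls without background subtraction, 0 with processed signals, 0 with the deposited values, 1 with no filter (more probes tested) and 120 with the replicate block. Amygdala against cortex gave 132 with processed signals, 132 with the deposited values and 331 with the block. Hippocampus against cortex gave 11 without background subtraction, 9 with processed signals, 8 with the deposited values, 16 with the stricter filter (fewer probes tested) and 73 with the block. Left against right cortex gave 1 with processed signals and 1 with the deposited values. The block moved no other count of calls by over 1.5 times.

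A 1.5-fold minimum, which can only lower a count, left 40 for strain (23 with a symbol, against 354 with processed signals, a combination chosen after the data were seen), 37 and 20 for amygdala and hippocampus against cortex, 661 for age, 187, 70, 253 and 60 at 6 weeks and 142, 178, 108 and 106 at 18 weeks. Which values and replicates the study's t-test used is not known here. The methods' t-test was run unpaired on channel values after loess and quantile scaling, so its counts need not be the study's. With 2 arrays per strain, at its own threshold, it gave 741, 562, 873 and 927 in the 4 regions at 6 weeks and 409, 531, 477 and 710 at 18 weeks. Against these stand 177 by chance, and after Benjamini-Hochberg it gave 0 in each. Over 8 arrays per strain at one age it gave 3760 at 6 weeks and 3389 at 18 weeks, and 3840 and 3333 after Benjamini-Hochberg, over arrays of 2 pools in 4 regions that are not independent replicates.

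With a pool left out, fewer arrays being tested, counts ranged from 6437 to 7603 for strain, 0 to 107 for strain by age, 3 to 230 for amygdala and 1 to 81 for hippocampus against cortex, 0 to 1 for left against right and 6248 to 6948 for age. With an array left out they ranged from 745 to 1948, 60 to 340, 380 to 2448 and 82 to 166 at 6 weeks, and from 381 to 1699, 166 to 1906, 153 to 897 and 379 to 430 at 18 weeks. The 52 strain genes and 41 age genes named stayed called without each pool. They were picked among called genes, most by size of change, so this is weak support. A dye bias or a slide effect would also stay with a pool left out.

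Called lists fell to 0 for strain, 0 for strain by age and 0 for age with a correlation estimated from the pool means, and to 0, 2 and 0 with one from 16 arrays, where blood (adjusted p = 0.0136) and immediate early genes (0.0230) stayed for strain by age. The block left 1 for age. The permutation p of the richest window fell to 0.003 (30 Mb) and 0.001 (15 Mb, the smallest possible) with the fold minimum (chromosome 1), 0.018 and 0.01 with no filter (chromosome 6), and 0.028 and 0.008 with processed signals and the fold minimum (chromosome 1), the last 0.31 and 0.061 (chromosomes 1 and 2) with globin genes counted once. Fisher's p for chromosomes 1 and 5 was 0.0372 with no filter, the share being lower on them. For the fixed window of 30 Mb on chromosome 1 it was 0.0142 with no filter, with 28.39% called inside against 34.39% outside.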
